A study of Mus musculus with 18 samples.

How the data were processed

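Expression was measured in 18 mouse hippocampus samples, 1 Affymetrix probe set array per sample, from 3 groups of 6: aged with impaired spatial memory, aged with unimpaired spatial memory, and young. Groups and sample numbers were taken from the sample titles. The series description speaks of animals with good and poor spatial memory, and the labels do not say whether each sample came from a separate animal. The p-values therefore measure the spread between these samples, part of which may be technical. The age of the animals, the hour of collection, the scan date and any batch are not given in the sources used here.

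The values are probe set intensity on a linear scale as the authors deposited them, made with MAS5 per the submitters' processing notes, which name no version. Total RNA was labelled with biotin by the manufacturer's standard procedure, per the labels' protocols. The intensity table, as deposited, holds 45101 probe sets with signals from 0 to 27601, and each array has a 2%-trimmed mean of 150. Detection calls, the scanner files and the software settings were not used here. An array has no read depth, so the number of arrays limits the precision.

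Each array was scaled to a trimmed mean of 500, leaving out 2% of values at each end, an offset of 16 was added and log2 was taken. A difference is thus on the log2(signal + 16) scale, which understates the change of dim genes. The 64 control probe sets and the 40% of the other probe sets with the lowest mean over all samples were left out, which left 27022 probe sets with a mean above 5.92. These steps, the tests, the gene lists and most alternatives were fixed before the data were examined, and those chosen later are named as such.

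Gene names came from the platform annotation, in which 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none. The symbols were updated through a RefSeq gene table of assembly GRCm38.p6, in which 34754 of the probe sets with 1 symbol were matched. A probe set with several symbols or none is unnamed here. The tested probe sets covered 13121 named genes, each represented by its probe set of highest mean. Where other probe sets of a named gene went the other way, the text says so. Genomic positions were not used, since no genome build is named for the values.

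limma 3.58.1 in R 4.3.3 was fitted to all 18 samples with 3 group means and moderated by empirical Bayes. The 4 comparisons were aged impaired against aged unimpaired, each aged group against young, and the mean of both aged groups against young. Tests were 2-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Errors printed after ± are standard errors of the fit unless an SD is named.

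Gene lists were written from textbook knowledge of hippocampal cell types, neighbouring tissue and pathways of ageing and memory. Of 36 lists, 34 were tested as lists. The list of sex-linked transcripts was kept outside the family, and the list of erythroid genes had fewer than 5 tested genes. Of 876 list entries, 768 had a tested probe set. Each list was tested with camera in limma against all other genes, with its preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 34 lists. The same test with a correlation estimated from the data, and fry in limma, were alternatives. A list's members were also counted with the p-values adjusted over the list alone. An exact permutation test of the mean of a list's genes per sample was added after seeing the data, since other splits of the samples called as many lists with the preset correlation.

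The genes named in each comparison, each on its probe set of highest mean, were the 10 with the largest rise and the 10 with the largest fall among those called, moved the same way in at least 5 of 6 samples, or 10 of 12 for both aged groups. Where fewer than 5 passed in a direction, the 10 of lowest unadjusted p were named as values. Up to 4 members of lowest unadjusted p were named from each list described, and all tested members of the sex list. The lists of clock, precursor and zinc genes were described although camera with the preset correlation passed them in no comparison, and 1 probe set of Hspa5 was named because it was among 3 calls.

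The alternatives were quantile normalization, offsets of 1 and 64, no filter and a filter of 60%, the sample number as a block, the 3' to 5' ratio of control transcripts as a covariate for RNA quality, array weights, trended and robust moderation, a fit of only the groups compared, and leaving out each sample. For lists, the mean of all probe sets of a gene was also used. Covariates for choroid plexus transcripts, for hybridisation spike-ins and for myelin minus presynaptic transcripts, and a fit of only the 12 arrays with high choroid plexus signal, were chosen after seeing the data. So were the fits of only the groups compared for single named genes, and the tests without each sample of the lists that an estimated correlation called.

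The fits were tested on simulated data with the real means and spreads of the 27022 probe sets, in which 200 probe sets were changed. Of 100 changed by 0.5 on the log2 scale, 38% were recovered for aged impaired against aged unimpaired, 48% for aged unimpaired against young, 45% for aged impaired against young and 64% for both aged groups against young. Of 100 changed by 1, the shares were 87%, 80%, 83% and 89%, with 7, 7, 7 and 8 false calls. A list of 20 genes shifted by 0.3 was called in each comparison, and 0 of the 34 unchanged lists were called. The simulated genes varied independently of each other, which real genes do not.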

Results

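The hippocampus, a brain region needed for spatial memory, was profiled in 18 mouse samples. There were 6 aged samples with impaired spatial memory, 6 aged samples with unimpaired spatial memory and 6 young samples. The median deposited signal per array lay between 23.5 and 30.5. Over the tested probe sets, each array correlated with the array most like it at 0.976 to 0.983. The median standard error of a difference between 2 groups was 0.124 on the log2 scale. Transcripts of the Y chromosome were present in every sample, with log2 values of 8.91 to 9.89 for Eif2s3y, 7.71 to 8.78 for Kdm5d and 6.99 to 7.81 for Uty. Xist, the transcript of the inactive X chromosome, lay between 5.22 and 6.80 on its tested probe set. Dimmer Xist probe sets that the filter left out lay between 4.06 and 5.40 and between 4.06 and 5.87. The range or level of Xist named below is that of the tested probe set. Second probe sets gave 6.65 to 7.95 for Eif2s3y and 6.78 to 7.85 for Uty.

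Transcripts of the choroid plexus, the secretory tissue that lies beside the hippocampus, varied widely within every group. The mean log2 value of the 19 choroid plexus genes was 9.56 ± 1.00 (SD, n = 6) in aged impaired, 8.79 ± 1.34 (SD, n = 6) in aged unimpaired and 9.56 ± 1.06 (SD, n = 6) in young samples. It was lowest in aged unimpaired replicates 4, 3 and 5 (7.26, 7.76 and 7.81), aged impaired replicate 5 (7.75) and young replicate 6 (7.76). An exact permutation test gave 2-sided p = 0.310 for aged impaired against aged unimpaired and p = 0.312 for aged unimpaired against young. The log2 ratio of 3' to 5' signal, a sign of RNA quality, was averaged over the control transcripts Gapdh and actin. Gapdh lay below 0 and actin above 0 (-0.28 and 0.89 in aged impaired samples). Their mean was 0.30 ± 0.05, 0.36 ± 0.06 and 0.31 ± 0.07 (SD, n = 6) in aged impaired, aged unimpaired and young samples. For the aged groups the exact permutation test gave p = 0.123. None of 28 such tests of array measures passed after adjustment, with a lowest adjusted p of 0.701.

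**Figure D1:**
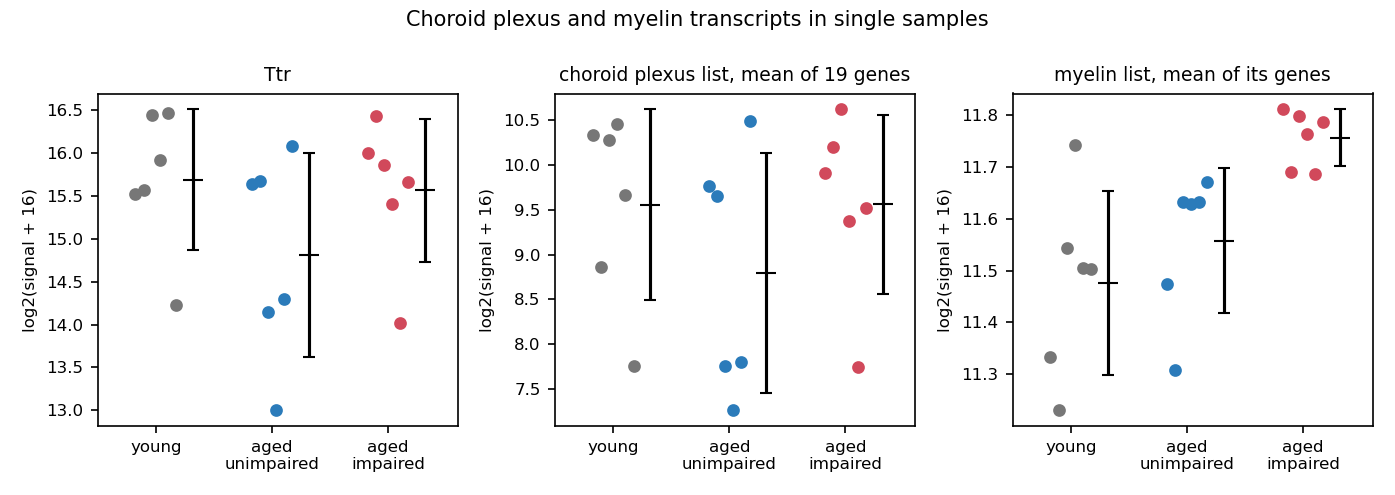
Log2(signal + 16) in each sample for Ttr, the mean of the choroid plexus list and the mean of the myelin list, by group. Each point is 1 sample, and the black mark with its bar is the mean and SD (n = 6). The choroid plexus mean spans 7.26 to 10.6 and is low in 3 aged unimpaired samples, 1 aged impaired and 1 young sample.

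The comparison that the series describes set aged impaired against aged unimpaired samples. Dbp, a transcription factor driven by the circadian clock, rose in the aged impaired samples. Its probe set of highest mean was 1.54-fold higher (log2 difference 0.62 ± 0.07, n = 6 per group, adjusted p = 0.00288), and all 6 impaired samples lay above all 6 unimpaired samples. A second probe set rose by 0.56 ± 0.07 (adjusted p = 0.00646). Hspa5, the main chaperone of the endoplasmic reticulum, fell by 0.56 ± 0.09 on 1 of its 3 tested probe sets (adjusted p = 0.0462), which was singled out after its value was seen. The Hspa5 probe set of highest mean had a difference of -0.38 ± 0.09 (adjusted p = 0.271), and the last probe set one of 0.08 ± 0.12. With the sample number as a block, and in the fit of only the groups compared, 0 probe sets were called, with Dbp at adjusted p = 0.0858 and 0.0877 (range over 14 alternatives 1.25e-04 to 0.326).

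These 3 probe sets were the calls among 27022, beside 2185 at an unadjusted p under 0.05, where chance gives 1351.1. Groups did not overlap for 142 probe sets, or 0.526%, where chance gives 0.216%. No other gene passed. The genes of lowest p with a higher mean in the impaired samples were St8sia6, a sialyltransferase (log2 difference 0.42 ± 0.08), Wnt9a (0.81 ± 0.15), Havcr2, an immune receptor of microglia (0.60 ± 0.11), Kcng2 (0.32 ± 0.07), Stxbp2 (0.58 ± 0.13), Qk, a splicing regulator of oligodendrocytes (0.34 ± 0.07), Xkr6 (1.01 ± 0.23), Mog, a myelin protein (0.36 ± 0.08), and Mcm3, a replication helicase subunit (0.70 ± 0.16). Those with a lower mean were Irf2bpl (-0.42 ± 0.08), B3galt2 (-0.74 ± 0.15), Specc1 (-0.33 ± 0.07), Lix1l (-0.41 ± 0.09), Manf (-0.36 ± 0.08), Arl15 (-0.70 ± 0.16), Fam171a2 (-0.50 ± 0.12), Rasl10a (-0.44 ± 0.10), Pomt1 (-0.51 ± 0.12) and Klhl7 (-0.26 ± 0.06). Their adjusted p ran from 0.122 to 0.266. Another probe set went the other way for St8sia6, Qk, Mcm3 and Specc1. The choroid plexus mean was 0.77 higher in the impaired samples (exact permutation p = 0.310).

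Genes of protein folding were lower as a list in the aged impaired samples. Of 29 chaperone genes, 22 had a lower mean, with a median difference of -0.15. Over all genes 0 were called on their highest probe set, and 8 fell when adjusted over the list alone. Among them were Manf, a secreted factor of endoplasmic reticulum stress, Hspa5, Creld2 (-0.42 ± 0.12) and Hspa8, a cytosolic chaperone (-0.26 ± 0.08, with a dim second probe set near 0 at 0.01 ± 0.26). The list passed camera (adjusted p = 9.41e-09) and also passed at adjusted p = 0.0145 with an estimated correlation. The exact permutation test of the list's mean gave p = 0.0022, the smallest that 6 against 6 samples allow (adjusted p = 0.0368).

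**Figure D2:**
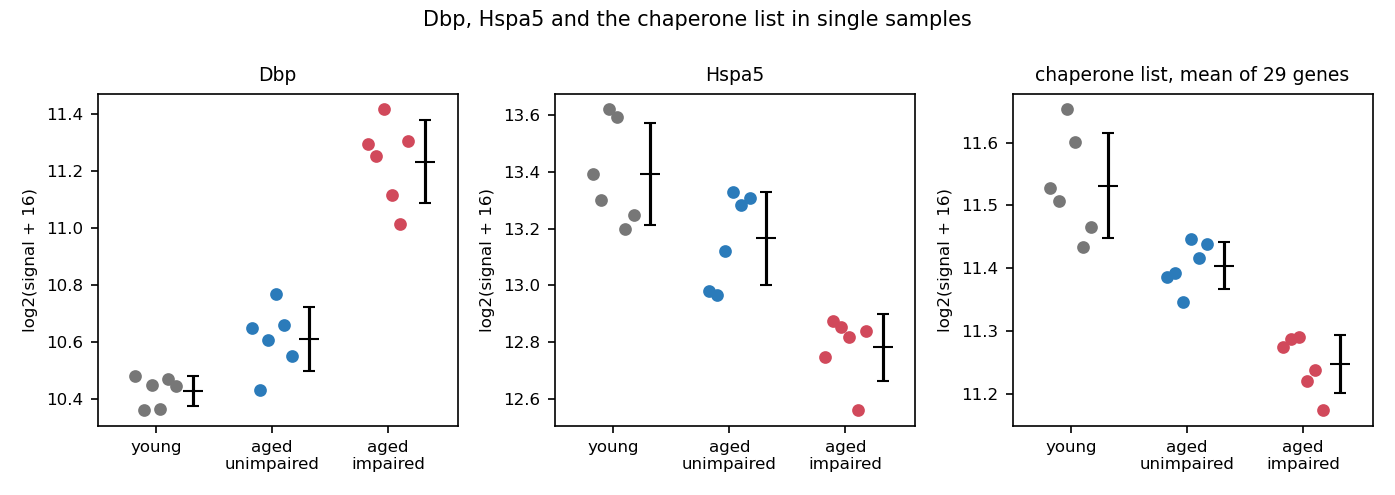
Log2(signal + 16) in each sample for Dbp, Hspa5 (its probe set of highest mean) and the mean of the 29 chaperone genes, by group. Each point is 1 sample, and the black mark with its bar is the mean and SD (n = 6). Dbp averages 11.2 in aged impaired, 10.6 in aged unimpaired and 10.4 in young samples.

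Myelin genes were higher as a list. Of 19, 16 had a higher mean in the impaired samples, with a median difference of 0.21, 0 were called over all genes and 2 rose when adjusted over the list alone. Mog, Mag (0.50 ± 0.14), Opalin (0.36 ± 0.12) and Gjb1 (0.30 ± 0.13) had the lowest p. The list passed camera (adjusted p = 9.02e-06), but adjusted p = 0.458 with an estimated correlation. Its mean passed the exact permutation test (p = 0.0022, the smallest, adjusted p = 0.0368). All 11 marker genes of CA1, a hippocampal subfield, had a lower mean, with a median difference of -0.25, 0 calls over all genes and 3 that fell when adjusted over the list alone. Mpped1 (-0.27 ± 0.07), Fibcd1 (-0.43 ± 0.13), Ccn3 (-0.34 ± 0.12) and Gpr161 (-0.25 ± 0.11) had the lowest p. The CA1 list passed camera (adjusted p = 5.03e-05), with adjusted p = 0.0698 with an estimated correlation and an adjusted p of 0.0736 in the exact permutation test of its mean.

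Another 7 lists passed camera with the preset correlation and not with an estimated one, and none had a gene called over all genes. Higher were choroid plexus genes (median 0.76, 19 of 19, adjusted p = 0.687 with an estimated correlation), microglia genes (median 0.23, 21 of 24, adjusted p = 0.687), lysosome genes (median 0.09, 20 of 23, adjusted p = 0.687), interferon-induced genes (median 0.20, 19 of 22, adjusted p = 0.687) and glucocorticoid-induced genes (median 0.10, 14 of 20, adjusted p = 0.536). Lower were presynaptic genes (median -0.07, 18 of 23, adjusted p = 0.568) and immediate early genes (median -0.04, 15 of 24, adjusted p = 0.504). Adjusted over the list alone, 1 glucocorticoid-induced gene rose and 0 genes of the other 6 lists passed. Examples were Ttr (0.76 ± 0.51), Tyrobp (0.35 ± 0.14), Ctsd (0.27 ± 0.12), Ifitm3 (0.45 ± 0.19), Nfkbia (0.37 ± 0.09), Slc17a7 (-0.27 ± 0.10) and Nr4a2 (-0.35 ± 0.10). Of 100 splits of the 12 aged samples, 30 called 10 or more lists, so the number of lists is within what chance gives. With the myelin minus presynaptic covariate 0 probe sets and 2 lists were called, and without aged impaired replicate 2 the count of lists was 6.

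The second comparison set aged unimpaired against young samples. Clec7a, a phagocytic receptor of activated microglia, rose with age (log2 difference 2.10 ± 0.39, n = 6 per group, adjusted p = 0.0389). Klk6, a serine protease of oligodendrocytes, rose by 1.79 ± 0.32. Sphk1, which makes sphingosine 1-phosphate, fell by 1.29 ± 0.22. Sox11 and Dpysl3, genes of newborn neurons, fell by 0.47 ± 0.09 and 0.49 ± 0.08. Each moved the same way in all 6 aged samples. The young means of Clec7a, Klk6 and Sphk1 (6.08, 6.66 and 6.56) lay within the range of Xist, so the size of these differences depends on the offset, and no fold is given. The calls of Clec7a and Sphk1 ended under several alternatives, with adjusted p from 0.00898 to 0.423 and from 0.0108 to 0.137 over all those run. Those of Klk6, Sox11 and Dpysl3 ended under at least 1, with highest adjusted p of 0.423, 0.286 and 0.522.

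In all, 30 probe sets rose and 7 fell, which named 25 genes, and 10 of the risers were unnamed. At an unadjusted p under 0.05 there were 2214 probe sets. On their probe sets of highest mean, the other genes with the largest rises were Spag6 (1.39 ± 0.26), Pisd-ps3 (1.36 ± 0.13), the integrin Itgb2 (0.96 ± 0.14), Dmp1 (0.91 ± 0.16), Pcdhb9, a clustered protocadherin (0.82 ± 0.09), Lpxn (0.81 ± 0.15), AU020206 (0.79 ± 0.15) and Zc3hav1, an antiviral protein (0.73 ± 0.12), with adjusted p from 1.29e-04 to 0.0435. The probe set of Pisd-ps3 has an x suffix, given where probes match other transcripts too. A dim second probe set of Zc3hav1 went the other way. C3ar1, the receptor of a complement fragment, was singled out after its values were seen: 1 probe set rose by 1.15 ± 0.14 (adjusted p = 8.25e-04), and that of highest mean had a difference of 0.63 ± 0.22 (adjusted p = 0.417). H2aw also fell (-0.33 ± 0.06). Values that did not pass were Hyou1 (-0.41 ± 0.08), Gpr17 (-0.61 ± 0.12), 3110021A11Rik (-0.72 ± 0.14), Supt7l (-0.48 ± 0.10), Ears2 (-0.50 ± 0.11) and Dact1 (-0.64 ± 0.14), with adjusted p from 0.0512 to 0.0787. A dim second probe set of Ears2 went the other way. Without a filter 13 probe sets were called, and on the 12 arrays with high choroid plexus signal 5 were. Only 3 aged unimpaired and 4 young arrays were among those 12, so fewer samples were compared. With the choroid plexus covariate on all 18 arrays 47 probe sets were called. The count was 22, 19 and 21 without aged unimpaired replicates 1, 3 and 6, and 19, 16 and 16 without young replicates 2, 5 and 6.

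Microglia genes rose as a list in the aged unimpaired samples. All 24 had a higher mean, with a median difference of 0.60, 4 rose over all genes and 20 when adjusted over the list alone. Besides Clec7a, the complement gene C1qb (0.68 ± 0.12), Aif1 (0.66 ± 0.12) and Fcer1g (0.61 ± 0.11) rose. The list passed camera (adjusted p = 2.60e-31) and at adjusted p = 0.0420 with an estimated correlation. Of 18 genes of neurogenesis, 17 had a lower mean, 2 fell over all genes and 4 when adjusted over the list alone. Rrm2 (-0.58 ± 0.15) and Sox4 (-0.22 ± 0.07) followed Dpysl3 and Sox11 in order of p. That list fell (adjusted p = 7.73e-06), with adjusted p = 0.0190 with an estimated correlation. In the exact permutation test of list means both had adjusted p = 0.0552, and 0 lists passed.

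Single samples bear on the microglia list. Aged unimpaired replicate 6 stood apart as high for Clec7a (9.60), Tyrobp (10.89), Itgb2 (8.69) and C1qa (12.05), and young replicate 6 as low for Clec7a (4.39). Without aged unimpaired replicate 6 the median was 0.51 (adjusted p = 0.0364 with an estimated correlation). The call with an estimated correlation was lost without aged unimpaired replicates 2, 3 and 5 (adjusted p = 0.0712, 0.0514 and 0.0676) and without young replicates 1, 2, 3 and 6 (adjusted p = 0.0698, 0.0943, 0.0578 and 0.0680). With the preset correlation the adjusted p was at most 1.88e-26 without any 1 sample.

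Another 6 lists passed camera and lost the call with an estimated correlation, and 0 of their genes were called over all genes. Chaperone genes were lower (median -0.11, adjusted p = 0.0787 with an estimated correlation), among them Calr (-0.24 ± 0.07) and Hspd1 (-0.26 ± 0.07), and 3 fell when adjusted over the list alone. Interferon-induced genes were higher (median 0.32, adjusted p = 0.385, 0 over the list alone), among them Rtp4 (0.74 ± 0.22) and Irgm1 (0.29 ± 0.09). Complement and class I antigen genes were higher (median 0.22, adjusted p = 0.622, 5 over the list alone), among them B2m (0.60 ± 0.14) and H2-K1 (0.62 ± 0.15), whose probes can match related class I genes. Lysosome genes were higher (median 0.12, adjusted p = 0.638, 0 over the list alone), among them Ctsh (0.42 ± 0.13), whose second probe set had a difference of -0.02 ± 0.14. Collagen and matrix genes were lower (median -0.31, adjusted p = 0.638, 4 fell and 1 rose over the list alone), among them Col1a1 (-1.10 ± 0.31) and Col1a2 (-0.89 ± 0.25), while Sparc had a difference of 0.24 ± 0.08. Choroid plexus genes were lower too (median -0.84, 19 of 19, adjusted p = 0.743, 0 over the list alone), among them Ttr (-0.88 ± 0.51) and Igf2 (-0.84 ± 0.41).

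The third comparison set aged impaired against young samples, which are labelled unimpaired, so age and memory state differ together. Among named genes on their probe sets of highest mean, the largest rises were in Lcn2, an iron-binding protein of reactive astrocytes (2.70 ± 0.66, n = 6 per group, adjusted p = 0.0459), and in the microglial genes Cst7 (2.63 ± 0.39, adjusted p = 0.00209) and Clec7a (2.59 ± 0.39, adjusted p = 0.00209). Klk6 rose by 2.5045 (± 0.32, adjusted p = 4.34e-04). Manf and Hspa5, both of the endoplasmic reticulum, fell by 0.64 ± 0.08 and 0.61 ± 0.09. All 6 impaired samples lay outside the range of the 6 young samples for each of these genes. The young means of Lcn2, Cst7, Clec7a and Klk6 (4.92, 4.77, 6.08 and 6.66) lay within or below the range of Xist, so no fold is given and their order is not determined. The call of Lcn2 ended under several alternatives, with adjusted p from 0.0179 to 0.407 over all those run. Those of Clec7a, Cst7 and Klk6 ended under at least 1, with highest adjusted p of 0.145, 0.0722 and 0.0725. Those of Manf and Hspa5 held under all those run, with highest adjusted p of 0.0393 and 0.0447.

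Calls numbered 440 probe sets, of which 278 rose and 162 fell, and they named 357 genes. Over all called probe sets the largest rise was 3.22, on an unnamed probe set, and the largest fall was -1.52, on a probe set that was not the brightest of its gene. Other large rises were Lyz1 (2.03 ± 0.35), Ccl12 (1.96 ± 0.30), Lyz2 (1.58 ± 0.31), Tnni1 (1.4998 ± 0.33), S100a4 (1.42 ± 0.23) and Serpina3n, a protease inhibitor of reactive astrocytes (1.39 ± 0.21). Other large falls were Vegfc (-0.82 ± 0.14), Sdf2l1 (-0.78 ± 0.15), Traf4 (-0.78 ± 0.16), Gpr17, a receptor of oligodendrocyte precursors (-0.71 ± 0.12), Ffar2 (-0.69 ± 0.17), BC030500 (-0.68 ± 0.15), Rasl10a (-0.66 ± 0.10) and Rrm2, a subunit of ribonucleotide reductase (-0.65 ± 0.15). Their adjusted p ran from 0.00215 to 0.0478. Dbp rose by 0.81 ± 0.07 (adjusted p = 3.00e-05), and Arntl, a clock gene of opposite phase, fell by 0.39 ± 0.08 (adjusted p = 0.0249), with a dim second probe set at 0.11 ± 0.17. With the myelin minus presynaptic covariate 34 probe sets were called, and on the arrays with high choroid plexus signal, which are fewer, 55 were. With the choroid plexus covariate on all 18 arrays 546 were called. The count was 266, 270 and 228 without aged impaired replicates 2, 3 and 6, and 291, 292, 259 and 228 without young replicates 1, 3, 5 and 6.

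Of 24 microglia genes, 17 rose over all genes and 23 when adjusted over the list alone, with a median difference of 0.81, among them C1qb (0.95 ± 0.12), Fcer1g (0.77 ± 0.11) and Tyrobp (0.96 ± 0.14). Of 29 chaperone genes, 8 fell over all genes and 16 when adjusted over the list alone, with a median of -0.25, among them Calr (-0.34 ± 0.07) besides Sdf2l1, Manf and Hspa5. Of 18 neurogenesis genes, 3 fell over all genes and 6 when adjusted over the list alone, with a median of -0.19, namely Sox11 (-0.58 ± 0.09), Dpysl3 (-0.50 ± 0.08) and Rrm2. These 3 lists passed camera (adjusted p = 9.08e-29, 1.38e-13 and 6.09e-05) and kept the call with an estimated correlation (adjusted p = 0.0383, 0.00194 and 0.0275). The microglia list lost that call without aged impaired replicate 1 (adjusted p = 0.0592) and without young replicates 1, 2 and 3 (adjusted p = 0.0581, 0.0614 and 0.0562). They also passed the exact permutation test of list means (adjusted p = 0.0245 each), as did the interferon, lysosome, myelin and cholesterol lists (adjusted p = 0.0315 each).

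The other 8 lists that passed camera did not pass with an estimated correlation. Interferon-induced genes were higher (median 0.57, adjusted p = 0.179 with an estimated correlation), and Rtp4 (1.03 ± 0.22) and Ifitm3 (0.82 ± 0.19) were the 2 that rose, with 12 over the list alone. Lysosome genes were higher (median 0.21, adjusted p = 0.184), and Ctsz (0.88 ± 0.19), Gusb (0.43 ± 0.09), Man2b1 (0.43 ± 0.10) and Scarb2 (0.26 ± 0.06) were the 4 that rose, with 9 over the list alone. Second probe sets of Man2b1 and Scarb2 went the other way. Myelin genes were higher (median 0.32, adjusted p = 0.184), and Mog (0.46 ± 0.08), Mag (0.63 ± 0.14) and Aspa (0.62 ± 0.15) were the 3 that rose, with 6 over the list alone. Complement and class I antigen genes were higher (median 0.47, adjusted p = 0.261), and H2-K1 (0.83 ± 0.15), H2-D1 (0.83 ± 0.19) and B2m (0.60 ± 0.14) were the 3 that rose, with 4 over the list alone. Glucocorticoid-induced genes were higher (median 0.13, adjusted p = 0.179), and Lcn2, Zbtb16 (0.44 ± 0.10), Sgk1 (0.57 ± 0.14) and Nfkbia (0.36 ± 0.09) were the 4 that rose, with 5 that rose and 1 that fell over the list alone. Astrocyte genes were higher (median 0.08, adjusted p = 0.649), and Serpina3n and Gfap (0.77 ± 0.14) were the 2 that rose, with 4 over the list alone. Cholesterol synthesis genes were higher (median 0.13, adjusted p = 0.247) with 0 called and 1 over the list alone, where Fdft1 had a difference of 0.23 ± 0.06. Collagen and matrix genes were lower (median -0.20, adjusted p = 0.780) with 0 called and 2 that rose and 3 that fell over the list alone, where Col1a1 had a difference of -1.14 ± 0.31. The choroid plexus mean of these groups differed by 0.0041 (exact permutation p = 0.996).

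**Figure D3:**
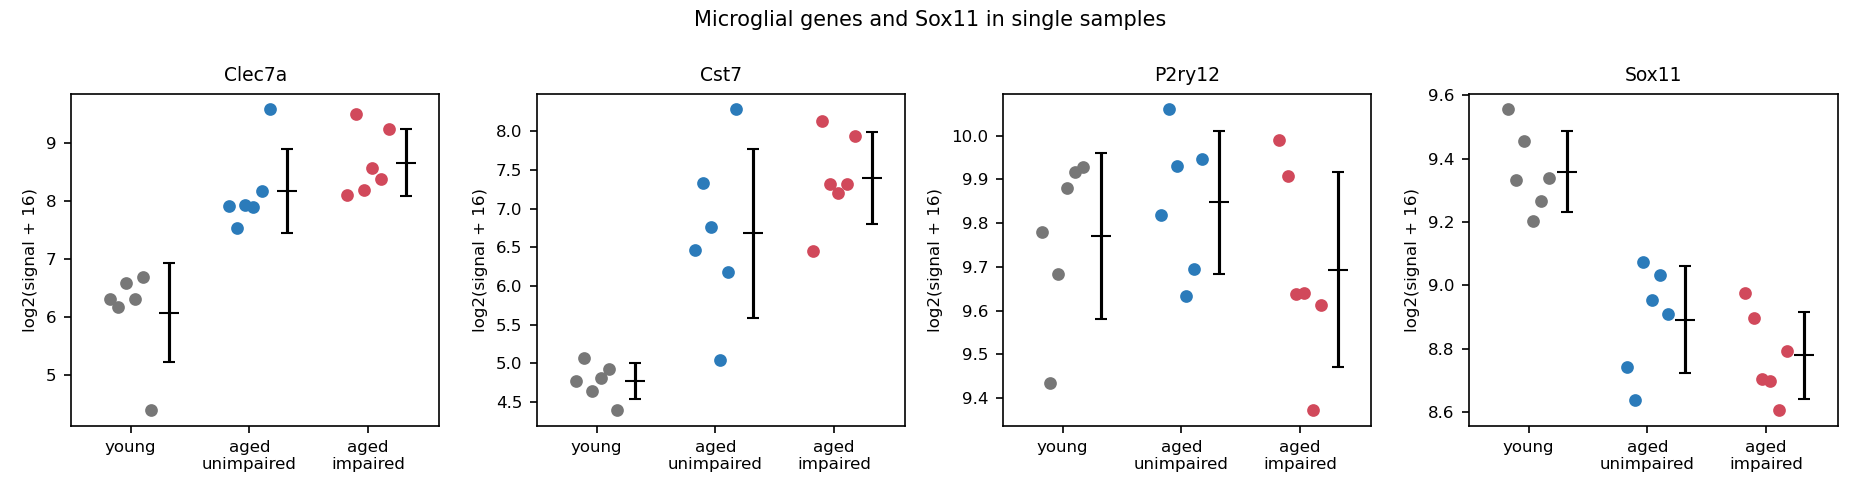
Log2(signal + 16) in each sample for the microglial genes Clec7a, Cst7 and P2ry12 and for Sox11, by group. Each point is 1 sample, and the black mark with its bar is the mean and SD (n = 6). Clec7a averages 6.08 in young, 8.18 in aged unimpaired and 8.67 in aged impaired samples, and Sox11 9.36, 8.89 and 8.78.

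Both aged groups together were set against young samples. Among named genes on their probe sets of highest mean, the largest rises were in Lcn2 (2.498 ± 0.57, n = 12 aged and 6 young), Clec7a (2.34 ± 0.34), Cst7 (2.27 ± 0.34) and Klk6 (2.15 ± 0.28), followed by Lyz1 (1.84 ± 0.30), the chemokine Ccl12 (1.68 ± 0.26), Cd37 (1.44 ± 0.30), Lyz2 (1.43 ± 0.26), Pisd-ps3 (1.36 ± 0.11) and Spag6 (1.33 ± 0.23). On the same probe sets, the largest falls were in Sphk1 (-0.83 ± 0.19), Ffar2 (-0.70 ± 0.15), Gpr17 (-0.66 ± 0.10), Vegfc (-0.62 ± 0.12), Rrm2 (-0.61 ± 0.13), 3110021A11Rik (-0.58 ± 0.12), Sdf2l1 (-0.56 ± 0.13), Dact1 (-0.54 ± 0.12), Sox11 (-0.52 ± 0.08) and Slc2a6 (-0.52 ± 0.11). The order of the first 4 genes is not determined, since their young means lay at the level of Xist. That of Sphk1 lay there too, so the size of its fall depends on the offset. The fall of Sphk1 was larger in aged unimpaired than in aged impaired samples, and it was not among the falls named for the latter. The calls of Lcn2 and Sphk1 ended under several alternatives (adjusted p from 0.0183 to 0.345 and from 0.0252 to 0.214). Only Cst7 and Pisd-ps3 kept the call under all alternatives run for them (highest adjusted p 0.0210 and 0.00413). The highest adjusted p of each other gene named here was 0.0630 or more. Cd37 and Vegfc moved the same way in 11 of 12 aged samples, and the other 18 genes in 12 of 12.

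Calls numbered 256 probe sets, of which 166 rose and 90 fell, naming 205 genes, beside 3632 at an unadjusted p under 0.05. Over all called probe sets the largest rise was 2.62, on an unnamed probe set, and the largest fall was -0.90, on a probe set that was not the brightest of its gene. The adjusted p of the named genes was at most 0.0474. Of 24 microglia genes 15 rose over all genes and 23 when adjusted over the list alone, among them C1qb (0.82 ± 0.10) and C1qa (0.82 ± 0.12). Of 29 chaperone genes 4 fell and 12 when adjusted over the list alone, among them Manf (-0.47 ± 0.07), Hspa5 (-0.42 ± 0.08) and Calr (-0.29 ± 0.06). Of 18 neurogenesis genes 3 fell and 5 when adjusted over the list alone. The 3 lists had medians of 0.70, -0.19 and -0.16, passed camera (adjusted p = 9.66e-34, 7.50e-11 and 3.58e-06) and kept the call with an estimated correlation (adjusted p = 0.0210, 0.00613 and 0.00924). The remaining 8 lists that passed camera lost the call there, with adjusted p from 0.181 to 0.652 with an estimated correlation. The count was 160 without aged unimpaired replicate 3, and 153, 160, 146, 136 and 116 without young replicates 1, 2, 3, 5 and 6. On the arrays with high choroid plexus signal, which are fewer, it was 21, and with the myelin minus presynaptic covariate 78. With the choroid plexus covariate on all 18 arrays it was 309. Without a filter it was 131, and with the sample number as a block 141.

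The 8 were the interferon (1 rose, 11 over the list alone), complement and class I antigen (3 and 5), astrocyte (2 and 4), glucocorticoid (2 and 4), lysosome (0 and 6) and myelin (0 and 5) lists, all higher, the cholesterol list, which was higher with 0 called and 1 that rose and 1 that fell over the list alone, and the collagen and matrix list, which was lower with 0 called and 1 that rose and 4 that fell over the list alone. Rtp4 (0.88 ± 0.19), H2-K1 (0.72 ± 0.13), B2m (0.60 ± 0.12), H2-D1 (0.70 ± 0.16), Serpina3n (1.19 ± 0.18), Gfap (0.67 ± 0.12) and Zbtb16 (0.37 ± 0.08) rose. Values that did not pass were Scarb2 (0.24 ± 0.06, second probe set near 0), Mog (0.27 ± 0.07), Fdft1 (0.22 ± 0.05) and Col1a1 (-1.12 ± 0.26).

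The 2 comparisons of a single aged group with young samples shared 19 called genes in the same direction, and 0 in opposite directions. The 16 that rose in both included Clec7a, Klk6, Spag6, Pisd-ps3, Itgb2, C1qb, Aif1 and Fcer1g, and the 3 that fell were Sox11, Dpysl3 and H2aw. Independent lists of these sizes would share 0.292 rising and 0.0768 falling genes. Unchanged groups were simulated against the same young samples in 2 ways, 100 times each. With the deviations of the aged samples drawn with replacement, the median was 0 shared genes, but 2 of 100 simulations shared 19 or more, with a highest of 296. Drawing the same sample more than once shrinks the spread, so a second form with permuted deviations of random sign was chosen after that output was seen, but it called 0 genes in either comparison, so its 0 shared genes give no measure of sharing by chance. With the young samples parted into 3 and 3, each part serving 1 comparison, the 20 splits shared 0 to 3 genes with a median of 1. These fits called fewer genes, with medians of 3 rising for aged unimpaired and 18 for aged impaired samples against 18 and 213, so fewer could be shared. The counts were 9, 9, 12 and 7 without aged unimpaired replicates 1, 3, 5 and 6, and 6 each without young replicates 2, 5 and 6. Across 13121 genes, which are not independent replicates, the log2 differences correlated at 0.661, against a median of 0.509 (range -0.183 to 0.854) in the second form of the simulation and 0.328 with split young samples. In the first form 25 of 100 simulations had a correlation as high. Their covariance was 0.0291, against a median of 0.0126 in the second form, a difference of 0.0166, with simulated values from -0.0019 to 0.0307. The signs matched for 71.7% of genes, against a median of 66.3% (range 46.6% to 83.8%) in the second form. A share as high came up in 28 of 100 simulations of the first form. Whether a gene called in only 1 aged group differed between the aged groups is what the first comparison tested.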

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

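The tests of explanations below, and the covariates for choroid plexus and tissue makeup, were chosen only after the results were seen. The differences between the aged groups came from tests fixed beforehand.

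Between the 2 aged groups, 3 probe sets and 10 gene lists were called. Of 100 splits of the samples, 30 called as many lists. With the sample number as a block, and in the fit of only the groups compared, 0 probe sets were called. The log2 differences were 0.62 and 0.56 for the 2 called probe sets of Dbp and -0.56 for 1 of the 3 tested probe sets of Hspa5. The list medians were -0.15 for chaperones, 0.76 for choroid plexus, 0.10 for glucocorticoid-induced genes, -0.0369 for immediate early genes, 0.20 for interferon-induced genes, 0.0949 for lysosome, 0.23 for microglia, 0.21 for myelin, -0.0734 for presynaptic genes and -0.25 for CA1. Of these lists, the chaperone list alone kept its call with an estimated correlation.

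Dbp was higher in the impaired samples, by 0.62 ± 0.07. RNA quality as a covariate left the difference at 0.64 ± 0.08 (adjusted p = 0.00754) and choroid plexus signal left it at 0.62 ± 0.08 (adjusted p = 0.0122), which argues against either as the whole source. With the myelin minus presynaptic covariate it was 0.57 ± 0.09 and the call ended (adjusted p = 0.326, range over 14 alternatives 1.25e-04 to 0.326), as it did with the sample number as a block (0.62, adjusted p = 0.0858), in the fit of only the groups compared (0.62, adjusted p = 0.0877) and on the arrays with high choroid plexus signal (0.73, adjusted p = 0.0539), where the difference was as large or larger and its precision lower. The size hardly moved with the tissue covariate while its error grew. A remaining difference of 0.57 ± 0.09 argues against tissue makeup, as this covariate measures it, as the whole source. A part played by tissue makeup stays open, since the call ended and the rule for this test asked for it to hold. A shift of the whole clock between the groups, such as another hour of collection, may also play a part: the score of 13 other clock genes was 0.11 higher in the impaired samples (0.68 ± 0.09 against 0.57 ± 0.12, SD, n = 6, exact permutation p = 0.106), which leaves it open, and memory state itself could not be separated from it.

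The chaperone list was lower in the impaired samples, with a median of -0.15 and adjusted p = 0.0145 with an estimated correlation. With covariates, the median was -0.15 for RNA quality (adjusted p = 0.0430 with an estimated correlation), -0.18 for choroid plexus (0.0103) and -0.14 for tissue makeup (0.00914). These values argue against each as the whole source. A lower expression of folding genes in impaired animals may remain as a hypothesis, found and tested on the same samples. The hour of collection and the handling of the animals were not tested.

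The microglia list was higher in aged samples, with a median of 0.70. With covariates for choroid plexus and RNA quality the median was 0.74 (adjusted p = 0.0146 with an estimated correlation) and 0.65 (0.0188). The tissue makeup covariate was not tested for this list with an estimated correlation. It lowered the called probe sets of aged against young samples, over all those tested, from 256 to 78. The lists called with the preset correlation went from 11 to 10. These counts do not single out the microglia list. A higher share of microglia with unchanged expression would raise all members alike if microglia alone expressed them and signal followed amount equally. The 4 members typical of resting microglia were also higher, by 0.24 (exact permutation p = 0.00215), and the other 20 members by 0.92. The exact permutation p for the difference was 5.39e-05, the smallest that 12 against 6 samples allow. On that premise, which was not tested, these values argue against a higher share alone. A changed state of microglia with age, with or without a change in their number, may remain as a hypothesis.

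For the 3 comparisons with young samples, a chance split of these samples is unlikely to give the counts of called probe sets. Each real count was set among 100 splits, which cannot give a share below 1 in 100. The labels do not say whether each sample is a separate animal, so chance between animals was not tested. The highest count of another split was 1 against the real 37 for aged unimpaired against young, 4 against 440 for aged impaired against young and 2 against 256 for both aged groups against young. For aged impaired against aged unimpaired the highest other was 2 against the real 3, over 100 of 462 possible splits. That margin is 1 probe set, and the count was 0 in the fit of only the groups compared, so exclusion of chance is weak there. The count was also 0 with the sample number as a block, but these numbers did not pair the samples. In each of these 4 results 1 split, the real one, was as large. For the 19 shared genes the highest other was 0 and 1 split was as large, but 0 of the 99 other splits had a call in both comparisons, so this count could only be 0 and says nothing about sharing. Chance cannot be excluded for the counts of lists with the preset correlation. With aged impaired against aged unimpaired first and the comparisons with young samples after it, 30, 23, 28 and 29 of 100 splits called as many, with real counts of 10, 8, 11 and 11 and highest others of 23, 17, 19 and 18. Splits that call more lists than the real one may reflect genes that vary together between samples. With a correlation estimated from the data, the real groups gave 1, 2, 3 and 3 called lists. The splits were not run that way, so this was not tested for them.

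Single samples stood far from the other 5 of their group in 39 of 474 tests of named genes and array measures, or 8.23%, where chance gives about 1 in 20. Genes of a list vary together, so these tests are not independent. Aged unimpaired replicate 6 had 9 high log2 values: Manf 11.26, Ctsd 12.51, Tyrobp 10.89, Clec7a 9.60, Itgb2 8.69, Ctsh 9.98, Lcn2 9.53, Serpina3n 11.10 and C1qa 12.05. Young replicate 4 had 3 high values, Nfil3 8.29, Ctsa 10.86 and Ptprc 8.01, and 4 low ones, Klhl7 10.88, Sv2b 12.82, Tnr 8.997 and Per1 8.32. Aged impaired replicate 2 had high values of Creld2 (9.27), Nfil3 (8.45), Tsc22d3 (10.89) and Mt1 (15.25) and a low one of Nr4a3 (10.79).

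Aged impaired replicate 1 had high values of Sparc (12.65), S100b (12.255) and Per1 (9.58) and a low one of Ears2 (6.64). Aged impaired replicate 5 had high values of Kcng2 (9.39) and Slc2a6 (8.86) and low ones of F5 (6.65) and Ebp (9.27). The remaining values stood apart in the same way: 3110021A11Rik 7.08 low in aged impaired replicate 4, Lss 8.83 high in aged unimpaired replicate 2, Stxbp2 7.27 low and Pcdhb9 11.02 high in aged unimpaired replicate 3, Irf2bpl 10.34 and Slc17a7 12.72 low in young replicate 1, Klk6 5.86 and Dact1 7.97 low in young replicate 2, Gpr161 9.65 low in young replicate 3 and Clec7a 4.39 low in young replicate 6.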

How the results depend on the processing

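The covariates for choroid plexus, spike-ins and tissue makeup, the fit of arrays with high choroid plexus signal and the exact permutation of list means were chosen only after the data were seen. In the order aged impaired against aged unimpaired, aged unimpaired against young, aged impaired against young, and aged against young, the counts of called probe sets were 3, 37, 440 and 256, those of lists 10, 8, 11 and 11, and 19 genes were shared. The counts not given below stayed within 1.5 times these, and the cause of the changes was not tested. Some alternatives used fewer samples or another set of probe sets.

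Without a filter the last 3 counts were 13, 193 and 131 with 4 shared genes, and with the lowest 60% left out the first was 6 with 33 shared. The sample number as a block gave 0, 17, 240 and 141 with 6 shared. The RNA quality covariate gave 17 lists for the first comparison, 23 probe sets for the second and 8 shared genes. Array weights gave 57 for aged unimpaired against young and 30 shared, and trended robust moderation gave 9 and 58 for the first 2 and 38 shared. The choroid plexus covariate gave 3 lists for the first comparison and 30 shared genes, and the spike-in covariate 7 probe sets. The myelin minus presynaptic covariate gave 0 probe sets and 2 lists for the first comparison, 34 and 78 probe sets for the last 2 and 5 shared genes. The 12 arrays with high choroid plexus signal gave 0, 5, 55 and 21 probe sets, 4 lists for the first comparison and 1 shared gene. They were 5 aged impaired, 3 aged unimpaired and 4 young arrays. Fits of only the groups compared gave 0, 22 and 241. Lists called with an estimated correlation numbered 1, 2, 3 and 3, with fry 2, 3 and 5 for the first, second and last comparison, and with exact permutation 2, 0, 7 and 5.

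The direction of the camera test, which sets a list against all other genes, reversed for the choroid plexus list, with medians of 0.0265 and 0.0232 with its own covariate for the first 2 comparisons and 0.0279 on the arrays with high signal for the first, and for the myelin list with its covariate, with a median of 1.85e-04. These covariates are made from the lists themselves. A gene result counted as reversed when its sign changed and the main or the alternative fit called it. Sign changes of results called in neither were not counted. Of 267 gene results, 0 reversed in this sense under the 13 alternatives run for all comparisons, of which the filter of 60% covered 227. Of 197 in fits of only the groups compared, 0 reversed. Single genes were not tested without each sample. Under the 13, between 178 (high choroid plexus arrays) and 261 (offset of 1) kept their side of the threshold. Of 40 list results, 9 kept their call with an estimated correlation and 19 with fry.

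Leaving out single samples gave 2 to 4, 16 to 37, 228 to 467 and 116 to 274 probe sets, 6 to 14, 7 to 10, 8 to 13 and 9 to 12 lists and 6 to 20 shared genes. The sample numbers did not pair the samples: 0 of 18 same-number pairs of groups correlated above 0.1 (-0.247 to 0.0957). Signal over background limits dim genes, whose differences the offset shrinks.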

Other observations

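The test of the clock score named below was chosen only after the result was seen.

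Oligodendrocyte precursor genes and zinc handling genes had called members with no call of the list by camera with the preset correlation. Gpr17 and C1ql1 (-0.57) fell in aged impaired against young samples, while the 13 precursor genes had a median of 0.00 and a mean of -0.09 (camera adjusted p = 0.348). Slc30a1, a zinc exporter, rose by 0.47 ± 0.08 in aged impaired against young samples (adjusted p = 0.00335), with a dim second probe set at -0.23 ± 0.30, and the zinc and metal list had adjusted p = 0.0861 with camera and 0.0123 with fry. In aged unimpaired against young samples the median of the clock genes was -0.02 while their mean was 0.00 and the test pointed up, with adjusted p = 0.714. The precursor list had a median of 0.02 and a mean of -0.02 between the aged groups (adjusted p = 0.812).

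Clock genes had differences of both signs between the aged groups. Besides Dbp, which was the 1 called, Npas2 had a difference of 0.30 ± 0.12, Arntl of -0.25 ± 0.08 and Nfil3 of -0.32, and second probe sets of Npas2 and Arntl went the other way. The list of 19 had a median of 0.07 (camera adjusted p = 0.698), while fry for changes in either direction gave adjusted p = 3.18e-10, a test that Dbp alone can carry. A score of the clock's phase without Dbp gave exact permutation p = 0.106.

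The 19 lists that camera with the preset correlation called in none of the 4 comparisons were those of antioxidant defence, calcium channels, chromatin, the clock, endothelial and mural cells, insulin signalling, interneurons, metal handling, oligodendrocyte precursors, oxidative phosphorylation, plasticity kinases, postsynaptic glutamate receptors, potassium channels, the proteasome, ribosomal proteins, senescence and DNA damage, CA3, the dentate gyrus, and thalamus and striatum. Their medians lay between -0.07 and 0.08, with a lowest camera adjusted p of 0.0758. Of these, fry called the metal list in aged impaired against young samples. Its test for changes in either direction called the lists of the clock, chromatin, precursors, metal handling, endothelial and mural cells, interneurons and the dentate gyrus in at least 1 comparison.

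Of the erythroid genes, a sign of blood left in the tissue, 4 were tested. In aged against young samples Hbb-b2, a beta globin, had a log2 difference of -0.61 ± 0.14 (adjusted p = 0.0526), with a second probe set at -0.14 ± 0.32. Alas2 had a log2 difference of -0.00 ± 0.36, Bpgm one of 0.06 ± 0.08 and Slc4a1 one of 0.17 ± 0.26.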
